A study of Mus musculus with 4 samples.

How the data were processed

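CD8 T cells sorted from mice infected with LCMV were measured by 10x 5′ V2 single-cell RNA sequencing in 4 libraries, 1 per group: endogenous GP33-specific cells at day 5, endogenous GP33-specific cells after day 45, donor P14 cells from recipients, and host GP33-specific cells from the same recipients. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the values themselves, which are whole numbers with totals that differ between barcodes. The submitters' processing notes list Cell Ranger 7.0.1, Seurat 4 and the mm10 build, with no role or order. The annotation release and the cell-calling settings are not given in the sources used here. Genes were taken by the identifiers and symbols deposited with the matrices, and coordinates are from GENCODE vM21 on GRCm38 (mm10). In the order day 5, late, labelled donor and labelled endogenous, 3712, 5428, 13532 and 11173 barcodes were deposited, with medians of 7564, 3344, 4859.5 and 4479 UMIs. V(D)J contig sequences and surface-protein measurements were not used here.

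Barcodes with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs passed (3495, 5271, 13287 and 11074). Scrublet, run per library in scanpy 1.11.5, called 0, 1, 0 and 1459 doublets. Doublet removal thus took cells almost only from 1 library, and whether doublets were missed in the others or overcalled in that one was not tested. Keeping all doublets treats the 4 libraries alike and was run as an alternative. Cells with 3 or more UMIs over 17 B-cell, myeloid and erythroid genes were left out (819, 144, 938 and 439 cells), which removed 23.4% of day 5 cells against 2.73%, 7.06% and 4.57%, as were cells with no UMI of 5 T-cell genes (56, 3, 10 and 2). The kept cells numbered 2673, 5126, 12347 and 9176, with 21792733, 24462012, 74115958 and 45329450 UMIs and medians of 2455, 1499.5, 1865 and 1753 genes. Kept cells had median mitochondrial shares of 1.31%, 1.07%, 0.82% and 0.79%.

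For the receptor check, each cell was given the beta V segment and the alpha V family with most UMIs, and shares are of cells with such a UMI. The effective number of segments is the inverse of the summed squared shares. For shares of cells with a transcript, each cell was thinned at random without replacement to 2000 UMIs, and 203, 471, 655 and 171 cells below that depth were left out (2470, 4655, 11692 and 9005 cells remained). The Tcf7 gate holds cells with a Tcf7 UMI and none of Havcr2, and the Havcr2 gate the reverse. Shares have exact Clopper-Pearson intervals and differences of shares Newcombe intervals.

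UMIs were summed over the cells of a library and scaled to equal library totals (CPM). Comparisons between libraries set late against day 5, and labelled donor against labelled endogenous, as log2 of the ratio of CPM after adding 5 CPM to each; ratios in the text are without that addition, with exact conditional Poisson intervals. With 1 library per group no test across animals is possible, so no p-value is given for these comparisons. Fold bounds against 0 UMIs take 3 counts over the group's sum as the floor. The median log2 fold over all genes, late against day 5, was 0.07 with CPM, 0.02 with TMM and −0.03 with median-of-ratios scaling. Named genes had at least 50 CPM and a UMI in at least 5% of cells in the higher library, and were the 12 with the largest log2 fold in each direction (8 within gates), without receptor and immunoglobulin segments, mitochondrial, ribosomal-protein, sex-linked and haemoglobin genes and clone-named models. Members of the inhibitory-receptor, exhaustion-factor and stem-like lists were named as well; single members named from other lists were chosen after their values were seen.

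The 22 gene lists covered stem-like and memory genes, inhibitory receptors, exhaustion transcription factors, cytotoxic effectors, circulating effector and KLR genes (killer-cell lectin-like receptors), cytokines, chemokines, homing, cell cycle, interferon-stimulated genes, glycolysis, oxidative phosphorylation, immediate early genes with AP-1, heat shock, mitochondrially encoded genes, MHC class I, other cell types (B, myeloid, NK, CD4 T, erythroid with platelet) and sex-linked genes. A member was measured with at least 5 CPM in either library. Aldoa, whose symbol has more than 1 identifier, and Mx1, absent from the matrices, were not matched. Each list's median log2 fold was set against 10000 random lists of genes within 50 places in the order of expression, with an interval over its genes from order statistics; genes are not independent replicates.

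The gates were compared across the 4 libraries with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, library as a block, 8 sums) with Benjamini-Hochberg adjustment at 0.05, two-sided, and lists with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation. The sums held 928, 1053, 3550 and 2946 cells of the Tcf7 gate and 849, 1689, 2995 and 1681 of the Havcr2 gate, at full depth. Named genes there were the 12 with the largest fold in each direction among genes past the threshold with a mean log2 CPM of at least 5 and the same direction in all 4 libraries; 1 of them is not reported here. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at a resolution of 0.8, and were named from 11 marker lists by a mean log2 fold of at least 0.5, with at least 3 detected markers and no other list with more markers among the 10 leading genes. Where no marker was among those 10, a lead of 0.5 over the next list was asked for as well, a rule set after the clusters were first seen. The largest stem-like cluster (5296 cells, 18.1% and 30.4% of the recipients' libraries) led the naive-like list by little, with mean log2 folds of 1.37 and 1.24.

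The groups, comparisons, tests, lists, filters, named-gene rule and alternatives were fixed before the data were examined, apart from the cluster-naming lead and 2 alternatives. The first leaves out the filter on other cell types and was added after its effect at day 5 was seen. The second starts the clustering from 3 other random starts, and was added after rounding differences between otherwise equal computations had given different clusters; distances between cells were then computed in integers, so that the clusters do not depend on the processor. The alternatives fixed beforehand were unthinned cells, 3000 UMIs, a Slamf6 gate, TMM, size factors, doublets kept, stricter cell filters (1000 genes, under 5% mitochondrial), the mean of cell CPM, a pseudocount of 1, no CPM minimum, cells with no UMI of 5 cycling genes, DESeq2 1.42.0, no gene filter, no library block, thinned gates, leaving out each library, the cell-cycle list left out of the clustering, and resolutions of 0.5 and 1.2. The pipeline was tested on simulated data made from these counts. Intervals for planted folds held the true value in 88% to 96% of cases, and 3 of 40 and 1 of 40 unchanged lists fell outside the central 95% of random lists in the day and recipient comparisons. Those simulated pairs of libraries held counting error only, so they say nothing on variation between animals or libraries. In the gate test, 50%, 86%, 94% and 98% of genes planted at 1.5, 2, 3 and 4-fold were recovered, and 11 of 175 calls were false. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.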

Results

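Chronic infection with lymphocytic choriomeningitis virus (LCMV) turns antiviral CD8 T cells into exhausted cells, in which a Tcf7-expressing, stem-like pool renews cells that carry the inhibitory receptor Tim-3, the product of Havcr2. Single-cell 5′ RNA libraries were made from 4 sets of mouse CD8 T cells specific for the GP33 epitope. The first library holds endogenous cells from day 5 of chronic infection and the second holds endogenous cells from after day 45 (the late library). For the other two, Tcf7-positive, Tim-3-negative P14 cells (CD8 T cells with a transgenic receptor for GP33) were taken at day 5 of acute Armstrong infection and moved into mice at day 5 of chronic infection, and donor and host cells were collected from the same spleens 15 days later. These are called here the library labelled donor and the library labelled endogenous, because their receptor transcripts go against their labels. Each group had 1 library, so there are no replicates, and animal, sort and library preparation were not separated from the groups. In the order day 5, late, labelled donor and labelled endogenous, the libraries held 32971046, 25821478, 84397345 and 62443863 UMIs (unique molecular identifiers), and 2673, 5126, 12347 and 9176 cells were kept, with median depths of 7016, 3359.5, 4797 and 4287.5 UMIs. Intervals are 95% and cover counting error only.

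P14 cells carry 1 known receptor, built from the beta segment Trbv13-3 and an alpha segment of the Trav14 family, so receptor transcripts point to the library that holds them. By that measure it was the library labelled endogenous. Among cells with a UMI from a beta V segment, Trbv13-3 led in 94.8% of the library labelled endogenous (8225 of 8679 cells, exact binomial interval 94.3 to 95.2) and in 11.1% of the library labelled donor (1360 of 12264, 10.5 to 11.7). It led in 16.8% of cells at day 5 (15.4 to 18.3) and in 6.77% of late cells (6.09 to 7.5). The Trav14 family led in 94.1% of cells with an alpha UMI in the library labelled endogenous (93.6 to 94.6) and in 13.2% in the library labelled donor (12.6 to 13.9), beside 18.1% at day 5 and 19.4% in the late library. Both segments led together in 89.6% of cells in the library labelled endogenous and in 3.74% in the library labelled donor. The library labelled donor used many segments, with an effective number of 8.33 beta segments and Trbv17 in front at 22.96% of cells, whereas the library labelled endogenous had an effective number of 1.11. The day 5 and late libraries had 9.27 and 7.69. The names of the deposited files for the recipients' libraries also go against the labels. Every direction given for these libraries below keeps the deposited labels, and reads the other way round for donor and host if the receptor is taken as the guide.

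**Figure D1:**
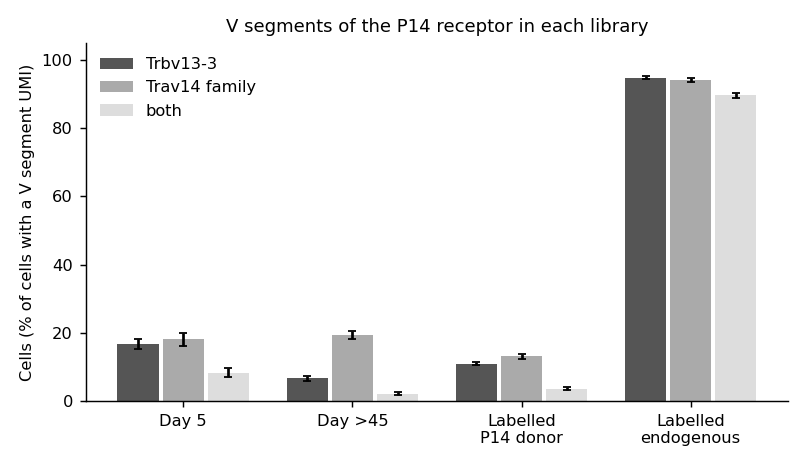
Percent of cells in which Trbv13-3 (of cells with a beta V UMI), the Trav14 family (of cells with an alpha V UMI) or both (of cells with each) led, for each library, with exact 95% binomial intervals as error bars. The library labelled endogenous stands at 94.8% and 94.1%, and the library labelled donor at 11.1% and 13.2%.

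The first comparison asked how virus-specific CD8 T cells late in chronic infection differ from those early in it. Late cells carried far more chemokine and inhibitory-receptor transcripts, and early cells were mostly dividing. Ccl5, Ccl3 and Ccl4, chemokines released by antigen-experienced T cells, were all higher late, as were the inhibitory receptors Pdcd1, Lag3, Tigit and Cd244a and the exhaustion regulator Tox. Mki67, Birc5 and Pclaf, which mark dividing cells, were lower late, as was Il2ra, the high-affinity interleukin 2 receptor chain of recently activated cells. Tcf7 itself was lower late in pooled counts and in the share of cells with a transcript. A class of naive-like cells, described with the clusters below, was found almost only at day 5. How far it adds to the Tcf7 difference was not tested.

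Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518 in GRCm38) stood at 39944 CPM (counts scaled to equal library totals) late and 742 CPM at day 5, a ratio of 53.8 (exact conditional interval 53.0 to 54.7). Cd7 (ENSMUSG00000025163, chromosome 11, 121036747 to 121039418), a co-receptor of T and NK cells, stood at 1712 and 31.0 CPM, a ratio of 55.3 (51.2 to 59.7). Csf1, a growth factor for macrophages, was 165-fold higher (117 to 242) and the protease inhibitor Serpina3g 116-fold (87.9 to 158). Ccl4 was 26.1-fold higher (25.01 to 27.3) and Ccl3 21.8-fold (20.6 to 23.03). Coch, which encodes a secreted matrix protein, had 5608 UMIs late and 1 at day 5, a ratio of 4996 (896 to 197369). Cd200r2, a relative of the inhibitory CD200 receptor, had 3745 late and 1 at day 5, and Penk, the enkephalin precursor, had 2909 and 1. Camk2n1, Cd200r1, Adgrg1 and Sept4 completed the 12 most increased, with log2 folds of 4.37 to 4.48. Among the genes lower late, Il2ra had 2 UMIs late and 1104 at day 5, a ratio of 620 in favour of day 5 (171 to 5.12e+03). The metallothionein Mt1 was 110-fold lower late (79.8 to 155), Pclaf 16.1-fold (15.1 to 17.2) and the survivin gene Birc5 15.3-fold (14.2 to 16.6). The rest were cell-cycle genes (Hist1h1a, Hist1h1b, Hist1h2ab, Rrm2, Ccnb2, Uhrf1 and Ccna2, log2 folds of −4.11 to −3.26) and Ggt1, of glutathione metabolism, at −3.28. Replication-dependent histone genes have near-identical copies, so the split of reads among them is uncertain.

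Pdcd1, which encodes PD-1, stood at 669 CPM late and 210 CPM at day 5, a ratio of 3.19 (3.09 to 3.30). Lag3 was 5.95-fold and Tigit 8.60-fold higher late, Cd244a, Cd101, Cd38, Entpd1 and Cd160 had log2 folds of 1.32 to 4.06, and Havcr2 had 0.85. Of 12 inhibitory receptors, 11 were higher late and Btla was lower (−0.54), and the median log2 fold was 2.28 (interval over genes 0.85 to 3.02), above every one of the 10000 random lists matched for expression. Tox was 4.61-fold higher (4.40 to 4.82), and Tox2, Nr4a2, Eomes and Ikzf2 had log2 folds of 1.91 to 3.00. The list of 12 exhaustion transcription factors had a median of 1.03 with 8 higher, but its interval (−0.25 to 2.16) included 0. Chemokines had the highest median of any list, 4.33 with 5 of 5 genes higher. In cells thinned to an equal depth of 2000 UMIs, a Pdcd1 UMI was seen in 33.0% of cells at day 5 and 68.5% late, a Tox UMI in 16.8% and 57.1%, and a Tigit UMI in 10.5% and 58.8%. The day 5 library held 51 B-lineage cells without T-cell transcripts (median depth 1913 UMIs), of which 25 reached 2000 UMIs. Of these 25, thinned to that depth, 1 held a Pdcd1 UMI, 1 a Tcf7 UMI and none a Havcr2 UMI. The other libraries held 0, 2 and 2 B-lineage cells without T-cell transcripts, so background from free RNA was not measured in them.

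Cell-cycle genes were lower late in 24 of 24 cases, with a median of −2.56 (−2.997 to −2.20), and 78.8% of late cells against 11.4% at day 5 held no cell-cycle UMI at full depth, which was not equal (medians of 3359.5 and 7016 UMIs). Among cells without one, of which the day 5 library held 304, the median was −1.24. How many of those cells were naive-like was not examined. Glycolysis genes, among them Ldha at a log2 fold of −1.99, had a median of −0.90 with 14 of 15 lower, but a smaller decrease among cells without a cell-cycle UMI. Heat shock genes such as Hsp90aa1 (−2.39) had a median of −1.36 with 8 of 8 lower. Interferon-stimulated genes had a median of 1.25 with 27 of 29 higher late, Isg15 at 1.62 among them, but the median was −0.05 once cells with a cell-cycle UMI were left out. MHC class I genes, led in abundance by H2-K1 at 1.92, had a median of 1.09 with 13 of 13 higher. Immediate early genes had 0.95 with 18 of 20 higher, of which Rgs1, a brake on chemokine signalling, showed 4.07. The MHC class I and immediate early medians were smaller among cells without a cell-cycle UMI. Cytotoxic genes had a median of 0.63 with 8 of 13 higher, and cytokines 1.01 with 7 of 7 higher, Ifng at 0.97. The stem-like list split, with 11 genes higher and 9 lower and a median of 0.34 (−1.30 to 1.38), so no direction is given, and the median was −0.41 among cells without a cell-cycle UMI. Il7r (2.20), Bcl2 (2.18) and Xcl1 (1.49), genes of survival and of dendritic-cell contact, were higher late, whereas Lef1 (−2.33), Satb1 (−2.49) and Ccr7 (−1.30), genes of lymph-node homing and of early T-cell identity, were lower. The circulating-effector list had a median of −0.33 (6 of 15 higher) and the homing list −0.10 (6 of 12). Oxidative phosphorylation had −0.47 and mitochondrially encoded genes −0.18, both within the central 95% of random lists.

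Tcf7-positive, Havcr2-negative cells made up 24.7% of cells at day 5 (23.01 to 26.4) and 17.6% late (16.5 to 18.7) at the equal depth, a difference of −7.10 points (−9.14 to −5.10), or −14.2 without thinning. Havcr2-positive, Tcf7-negative cells made up 14.7% (13.4 to 16.2) and 21.6% (20.4 to 22.8), a difference of 6.83 points (4.97 to 8.64), which was 11.6 at 3000 UMIs and 1.19 without thinning (−1.01 to 3.36). Within the Tcf7 gate, Ccl5 was 32.5-fold higher late (30.8 to 34.3), and Cxcl10, an interferon-induced chemokine, had a log2 fold of 4.43. Penk had 1230 UMIs late and 0 at day 5, at least 680-fold higher with 3 counts as the floor of the day 5 sum. Pclaf (−5.97) and Birc5 (−5.69) were the most decreased there. Stem-like genes had a median of 0.75 in this gate, inhibitory receptors 1.49 and cell-cycle genes −3.63. Within the Havcr2 gate, Cd7 (6.36), Coch (6.05), Ccl5 (5.86) and Csf1 (5.70) were highest, Cd200r2 was at least 527-fold higher (1985 UMIs late, 0 at day 5), and Mt1 (−5.36), Ly6c2 (−4.09) and Il2ra (−4.09) were lowest. Ly6c2 marks circulating effector and memory cells.

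**Figure D2:**
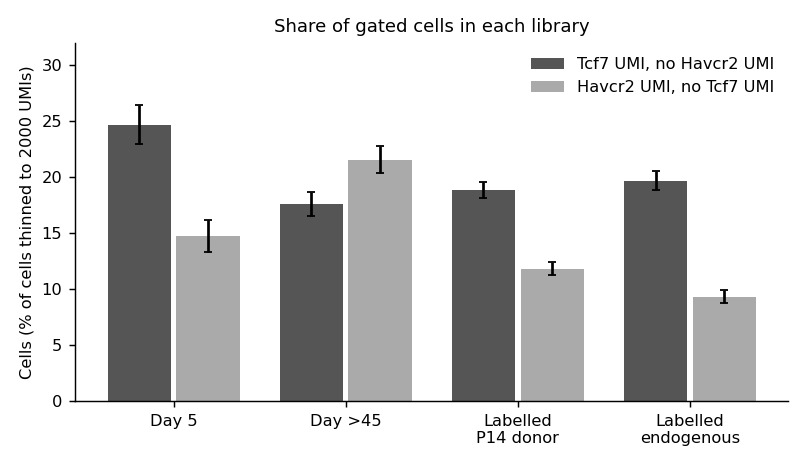
Percent of cells in the Tcf7-positive, Havcr2-negative gate and in the Havcr2-positive, Tcf7-negative gate for each library, after thinning to 2000 UMIs per cell, with exact 95% binomial intervals as error bars. At equal depth the Tcf7 gate holds 24.7% of cells at day 5 and 17.6% to 19.7% in the other libraries.

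The second comparison set the donor cells against the host's own cells after 15 days in the same chronically infected mice. It bears on whether cells that began in acute infection take up the same states as cells that met chronic infection from the start. Donor cells also differed from host cells by the Tcf7-positive, Tim-3-negative sort, the transgenic receptor and the transfer. The design does not separate these from the infection in which the cells began. The recipients' libraries were close to each other, with a correlation of 0.985 across 3624 genes, against 0.645 for day 5 and late (genes are not independent replicates). Their differences lay in circulating-effector and cell-cycle genes, higher in the library labelled donor, and in stem-like and interferon-stimulated genes, higher in the library labelled endogenous. The pooled level of Tcf7 hardly differed (log2 fold −0.04), nor did that of Tox (−0.11) or Eomes (−0.01).

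Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), a granule protease of killer cells, stood at 3095 CPM in the library labelled donor and 1195 CPM in the library labelled endogenous, a ratio of 2.59 (2.57 to 2.61). Cx3cr1, the fractalkine receptor of circulating effector cells, stood at 80.3 and 35.6 CPM (2.25-fold, 2.13 to 2.38), the proliferation marker Mki67 was 2.54-fold higher (2.43 to 2.66) and the carbonic anhydrase Car2 2.92-fold (2.72 to 3.14). The remaining 8 of the 12 most increased were cell-cycle genes, Hist1h2ab, Hist1h2ae, Hist1h1b, Cdca3, Cenpf, Ube2c, Ccna2 and Kif11, with log2 folds of 1.01 to 1.44. Genes lower in the library labelled donor were led by Podnl1, which encodes a matrix proteoglycan, at 17.3 against 58.1 CPM (3.36-fold, 3.14 to 3.59). Cd200, an immunoregulatory surface protein, was 2.40-fold lower (2.29 to 2.52) and Gpr183, a receptor that guides lymphocytes through lymphoid tissue, 2.27-fold (2.14 to 2.40). Tmem181a had −1.07, and the interferon-induced genes Ifit3, Ifit3b, Slfn5, Oas1a and Sp140 and the inflammatory caspases Casp1 and Casp4 had −0.97 to −0.76, beside Ctla2a at −0.81. Ifit3 and Ifit3b are near-identical copies, so their separate values are uncertain.

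Among stem-like genes, 17 of 20 were lower in the library labelled donor, with a median of −0.31 (−0.50 to −0.06), below every random list. Slamf6, a surface marker of stem-like exhausted cells, stood at 157 against 230 CPM, Id3, a regulator of memory precursors, at 141 against 201 CPM, and Il7r had a log2 fold of −0.52, whereas Lef1 (0.19) and Satb1 (0.33) were slightly higher. Circulating-effector genes had a median of 0.32 (0.02 to 1.78) with 13 of 16 higher. S1pr5, a receptor for exit from tissue, had 2664 UMIs in the library labelled donor and 12 in the library labelled endogenous, the transcription factor Zeb2 was 4.92-fold higher (4.43 to 5.48) and Klrg1, a marker of terminal effector cells, 5.86-fold (5.11 to 6.75). Interferon-stimulated genes had a median of −0.26 (−0.43 to −0.17) with 25 of 29 lower, and cell-cycle genes 0.69 (0.54 to 0.86) with 24 of 24 higher, which became 0.11 among cells without a cell-cycle UMI. Inhibitory receptors went both ways, with Havcr2 (0.37) and Cd160 (0.28) higher and Pdcd1 (−0.29), Lag3 (−0.24) and Ctla4 (−0.26) lower, and a median of 0.11. Exhaustion factors had a median of −0.01, but a mean above 0, and Ikzf2 (0.42) and Prdm1 (0.30) were higher. Cytokines had −0.30, homing genes −0.19 and immediate early genes −0.15. Medians were within 0.12 of 0 for cytotoxic (0.05), chemokine (0.01, mean below 0), glycolysis (0.04), heat shock (0.12), mitochondrially encoded (0.08) and MHC class I genes (−0.01), and oxidative phosphorylation changed sign (0.03, but −0.02 from the mean of cell CPM and −0.02 among cells without a cell-cycle UMI).

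**Figure D3:**
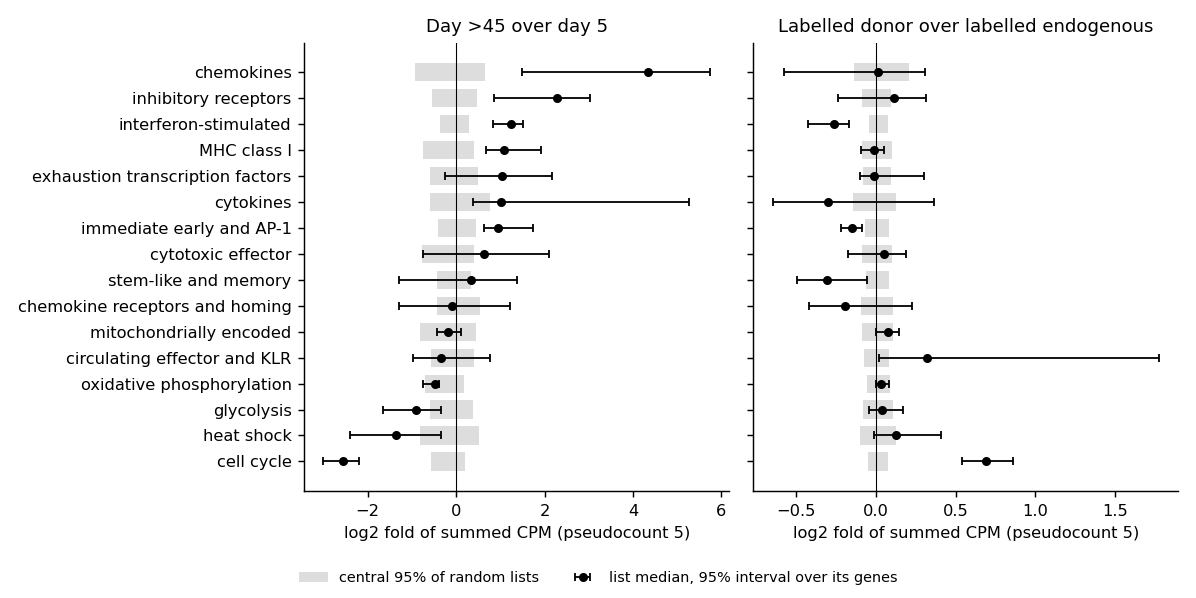
Median log2 fold of each gene list, late against day 5 on the left and labelled donor against labelled endogenous on the right, with 95% intervals over genes as error bars and grey bands for the central 95% of matched random lists. Inhibitory receptors (2.28) and cell cycle (−2.56) stand far from 0 on the left, and stem-like genes (−0.31) and cell cycle (0.69) on the right; the interferon-stimulated median on the left (1.25) falls to −0.05 in cells without a cell-cycle UMI.

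The Tcf7 gate held 18.9% of cells in the library labelled donor (18.2 to 19.6) and 19.7% in the library labelled endogenous (18.9 to 20.5), a difference of −0.84 points whose interval (−1.93 to 0.241) included 0. Some other settings gave larger differences, −3.12 points at 3000 UMIs (−4.37 to −1.87), −3.35 without thinning (−4.60 to −2.11) and −7.70 with a gate on Slamf6 (−8.90 to −6.49). The Havcr2 gate held 11.9% (11.3 to 12.5) and 9.35% (8.76 to 9.97), a difference of 2.5 points (1.66 to 3.34), or 5.94 without thinning. Within the Tcf7 gate, Gzma was 12.3-fold higher in the library labelled donor (11.4 to 13.2), at 661 against 54.0 CPM, and Gzmb, the other main granule protease, 3.62-fold (3.35 to 3.93). Cd7, Ccl5, Ccl4 and Ccl3 had log2 folds of 1.42 to 1.67 there, exhaustion factors were higher in 11 of 11 cases (median 0.17) and inhibitory receptors had a median of 0.39. Podnl1 (−1.47), Sostdc1 (−1.43), a secreted BMP antagonist, and Cd200 (−1.08) were lower. Within the Havcr2 gate, Ly6c2 (1.60), Hist1h3c (1.35) and Car2 (1.30) were higher and Podnl1 (−1.73), Tmem181a (−1.01) and Ctla2a (−0.93) lower. Podnl1 and Tmem181a thus differed by about as much in both gates, where the cell states are unlike.

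The third comparison set the Tcf7 gate against the Havcr2 gate inside each library, and it is the only one with replication, across 4 libraries. The recipients' libraries came from the same spleens, so the 4 libraries are not independent sets of animals, and they stand for different groups. Single genes passed in both directions, but no gene list kept its call with an estimated correlation among its genes. Id3, Il7r, Ccr7, Cxcr5 and Bcl6 rose in the Tcf7 gate, and Gzma, Gzmb, Ccl3, Ccl4, Fasl and Prdm1 fell. Slfn5 and Cxcl10, of the interferon-stimulated list, also rose, a list whose adjusted p was 5.72e-21 at the preset correlation and 0.313 at the estimated one. Tox showed no detectable difference between the gates across the libraries, which went both ways. Its log2 fold was 0.86 at day 5 and −0.25, −0.19 and −0.44 in the late, labelled donor and labelled endogenous libraries. Pdcd1 and Lag3 fell slightly in the Tcf7 gate, but Pdcd1 hardly at day 5 (−0.0045).

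Of 11013 genes tested with edgeR's quasi-likelihood test with library as a block, 1832 rose and 2064 fell at an adjusted p (Benjamini-Hochberg) under 0.05, and DESeq2 gave 1572 and 2020. Nsg2 (ENSMUSG00000020297), a vesicle protein gene, had a log2 fold of 5.997 ± 0.15 (SE, adjusted p = 2.72e-05), and Id3 (ENSMUSG00000007872) 5.75 ± 0.226 (adjusted p = 2.12e-04). Il7r had 5.01 ± 0.551 (adjusted p = 0.00344), Slfn5 4.65 ± 0.127 (adjusted p = 2.72e-05) and Xcl1, which attracts cross-presenting dendritic cells, 3.47 ± 0.632 (adjusted p = 0.0124). In the other direction, Ccl4 had −3.77 ± 0.329 (adjusted p = 0.00183), Gzma −3.54 ± 0.485 (adjusted p = 0.00581) and Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) −3.36 ± 0.302 (adjusted p = 0.00195). Genes named here were chosen among those with the same direction in 4 of 4 libraries. At day 5, however, Coch and Csf1 had log2 folds of only −0.03 and −0.12, so a shared direction is barely shown for them. Crtam, Cxcl10, Tnfsf8, Tespa1, Ms4a4c and Gpr183 were also among the 12 genes that rose most (3.03 to 3.66), and Ccl3, Adgrg1, Cd244a, Entpd1, Chn2, Csf1, Fasl, Coch and Sytl2 among the 12 that fell most (−3.77 to −2.95). The gates differ in cycling and in depth, and Tcf7 and Havcr2 were left out of the test. Counts fell to 1124 and 1183 without the late library, 527 and 575 without the library labelled donor, 601 and 648 without the library labelled endogenous, and 171 and 89 without the library block.

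**Figure D4:**
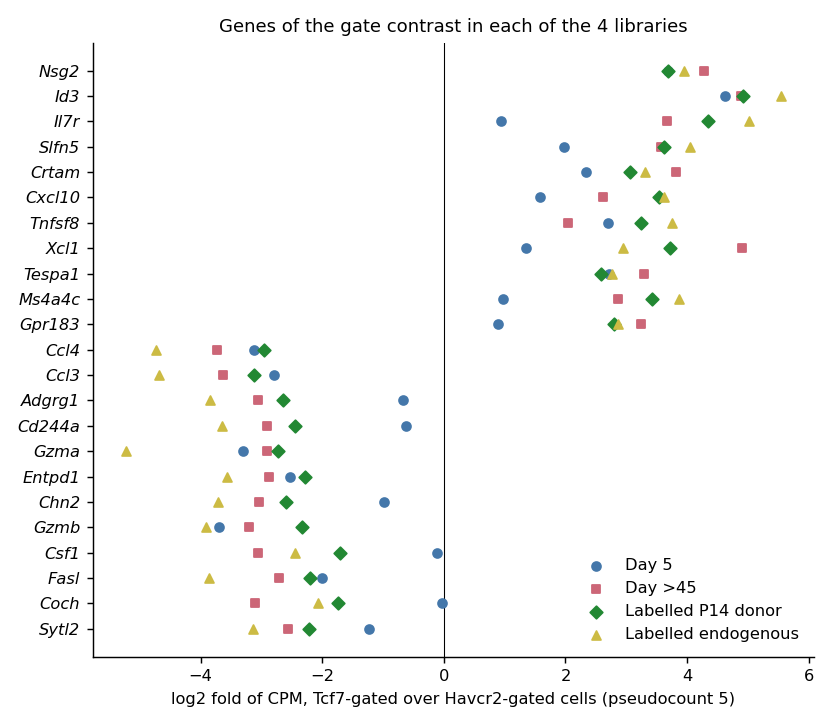
Log2 fold between the Tcf7 gate and the Havcr2 gate for the named genes, with 1 point per library (5 CPM added to each value). Genes were chosen among those with all 4 libraries on the same side of 0. The day 5 points of Coch (−0.03) and Csf1 (−0.12) lie near that line.

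Of 19 stem-like genes, 17 rose and none fell (18 and 0 adjusted over the list alone), with Ccr7 at 5.63, Cxcr5 at 4.01 and Slamf6 at 2.99, and camera with a preset correlation gave an adjusted p (Benjamini-Hochberg) of 3.11e-25, against adjusted p = 0.0738 with an estimated correlation. Only 9 rose past the threshold without the library labelled donor and 10 without the library labelled endogenous. Myb (2.13, adjusted p = 0.0619, higher in 4 of 4 libraries) and Bcl2 (0.64, adjusted p = 0.126, higher in 3 of 4) did not pass. Of 29 interferon-stimulated genes, 25 rose and none fell (26 and 1 adjusted over the list alone; camera adjusted p = 5.72e-21, adjusted p = 0.313 with an estimated correlation), and 15 rose without the library labelled endogenous. Cell-cycle genes fell in 21 of 24 cases (24 adjusted over the list alone; camera adjusted p = 2.08e-10, adjusted p = 0.419 with an estimated correlation), but in 4 without the library labelled donor, 5 without the library labelled endogenous and 13 without the late library. Cytotoxic genes fell in 9 of 13 cases and rose in 3 (none rose without either of the recipients' libraries), the same adjusted over the list alone (camera adjusted p = 3.25e-07, adjusted p = 0.313 with an estimated correlation). Inhibitory receptors fell in 8 of 11 cases, among them Pdcd1 (−0.79), Lag3 (−0.71) and Cd38 (−1.63), while Btla (1.49) and Ctla4 (0.55) rose. The counts were the same adjusted over the list alone (camera adjusted p = 0.00549, adjusted p = 0.454 with an estimated correlation). Of those 8, Pdcd1 (−0.0045), Cd160 (0.02) and Cd200r1 (0.38) did not clearly fall at day 5, whereas Lag3, Tigit, Cd244a, Entpd1 and Cd38 were lower there too. Only 3 fell without either of the recipients' libraries and 5 without the late library. Of 12 exhaustion factors, 4 fell and Batf (0.63) rose, 5 and 1 adjusted over the list alone; Prdm1, the gene of Blimp-1, had −3.45, and Tox did not pass (−0.02, adjusted p = 0.966, lower in 3 of 4 libraries). That list passed under camera (adjusted p = 0.0335, adjusted p = 0.433 with an estimated correlation), but not without the late library (0.0534) or the library labelled endogenous (0.0662). Without the day 5 library 9 fell and 2 rose (camera adjusted p = 0.00191), and without any one of the others 2 fell.

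Homing genes rose in 6 of 12 cases and fell in 3 (7 and 3 adjusted over the list alone; camera adjusted p = 7.66e-04, adjusted p = 0.367 with an estimated correlation), and mitochondrially encoded genes rose in 10 of 11 (11 adjusted over the list alone; camera adjusted p = 1.23e-05, adjusted p = 0.432 with an estimated correlation). Glycolysis genes fell in 9 of 15 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.375 with an estimated correlation), a call lost without the day 5 library (0.0709) or the library labelled donor (0.0563), and 3 fell without the late library and 2 without either of the recipients' libraries. Camera's adjusted p was above 0.05 for the circulating-effector list (0.410, 4 genes up and 3 down, 5 and 3 adjusted over the list alone), cytokines (0.783, 3 and 3, then 3 and 4), chemokines (0.0845, 2 and 3 in each), oxidative phosphorylation (0.0845, 1 and 4), immediate early genes (0.595, 7 and 5, then 7 and 6), heat shock (0.410, 0 and 3, then 1 and 3) and MHC class I (0.998, 1 and 2, then 1 and 0). The circulating-effector list passed without the day 5 library (0.0438), chemokines without the library labelled donor (0.00248) or endogenous (2.43e-05), and oxidative phosphorylation without the day 5 library (0.0130, 11 down). For circulating-effector, immediate early and MHC class I genes, camera's direction had the opposite sign to the list's median. Without the library block, 8 stem-like, 4 homing and 3 interferon-stimulated genes rose, and no cell-cycle, glycolysis or mitochondrially encoded gene passed.

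Unsupervised clusters, named from marker lists, separated stem-like, terminally differentiated-like, effector-like, cycling, interferon-responding and naive-like cells. An effector-like cluster, defined by circulating-effector genes such as Cx3cr1 and Klrg1 (so not independent of that list), held 9.24% of the library labelled donor (1141 cells, 8.74 to 9.77), but only 3 cells, or 0.0327%, of the library labelled endogenous, a difference of 9.21 points (8.71 to 9.73). It held 0.975% of late cells and none at day 5. Stem-like clusters held 24.7% of the library labelled donor and 39.5% of the library labelled endogenous, a difference of −14.9 points (−16.1 to −13.6), and 23.4% of late cells. The class joins 2 clusters: one led by Il7r and Id3 held 18.1% and 30.4% of the recipients' libraries and 5.23% of late cells, and one led by Xcl1 and Penk held 6.54%, 9.14% and 18.2%. Terminally differentiated-like clusters held 65.8% of late cells, 24.9% of the library labelled donor and 27.3% of the library labelled endogenous, but not in the same clusters. One led by Csf1, Coch and Cd200r2, whose 10 leading genes held 4 T-cell receptor gamma genes and no marker of the class (it was named by a mean log2 fold of 1.11 over the markers), held 57.8% of late cells (97.3% of its cells were late) and under 1% of each recipients' library, and one led by Cd7 and Cxcr6 held 7.37% of late cells and 24.1% and 26.04% of the recipients' libraries. Cycling clusters held 75.9% of cells at day 5, 3.24% late, and 13.7% and 6.09% in the recipients' libraries. Interferon-responding clusters held 3.66% of the library labelled donor and 5.07% of the library labelled endogenous, and clusters that met no marker rule 23.7% and 21.9%; the difference in the latter, 1.79 points, changed sign from another random start of the clustering (−0.706) and with doublets kept (−1.89). Cluster borders moved with the random start by more than counting error: over 3 other starts the stem-like difference ran from −13.0 to −11.95 points (−8.91 at a resolution of 1.2 and −7.17 with doublets kept, which treats the libraries alike), the interferon-responding difference from −4.65 to −0.0853 (−7.09 and −6.15 under those 2 settings) and the effector-like difference from 8.49 to 9.35. The cycling difference between the recipients' libraries, 7.57 points, was 7.50, 4.98 and 4.92 over those 3 starts. The naive-like class held 22.2% of day 5 cells and at most 0.154% of the others. Lef1, Satb1 and Ccr7, which were lower late, are on the naive-like marker list, as is Il7r, which was higher late.

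**Figure D5:**
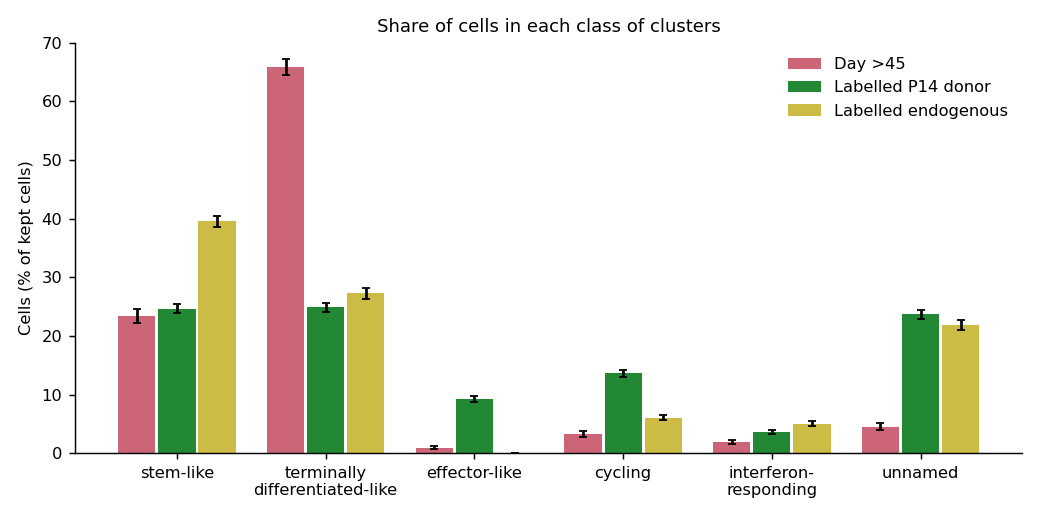
Percent of cells of the late library and of the recipients' libraries in each class of clusters, with exact 95% binomial intervals as error bars. The effector-like class holds 9.24% of the library labelled donor and 0.0327% of the library labelled endogenous.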

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

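The test that reassigned the gate labels within libraries was chosen after the gate result was seen. The 4 libraries allow 8 such assignments, the real one included. The real one gave 3896 genes past the threshold and the highest of the others 0; assignments with as many numbered 1, and 8 are too few for a share under 0.05.

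A set of 4 genes stood apart because the day 5 library ran one way between the gates and the other 3 libraries ran the other way, by at least 0.5 on the log2 scale in each. Cd7, a co-receptor of T and NK cells, was higher in the Tcf7 gate at day 5 (log2 fold 0.83) and lower in that gate late (−2.59), in the library labelled donor (−2.49) and in the library labelled endogenous (−3.93). Tox2, a relative of the exhaustion regulator Tox, had 0.99 at day 5 and −0.998, −1.64 and −2.03 in the others. Egr1, an early-response gene downstream of the T-cell receptor, had 0.77 and −0.79, −0.65 and −0.78, and Vamp5, a vesicle-fusion gene, had 0.51 and −0.77, −0.51 and −0.67. None of the 4 passed edgeR's test across libraries (adjusted p from 0.0840 for Cd7 to 0.317 for Egr1). The difference between day 5 and the other libraries was not tested, since day 5 has 1 library, and no biological explanation was tested. No gene met the same rule for any of the other 3 libraries.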

How the results depend on the processing

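The tests without the filter on other cell types and those from other random starts of the clustering were chosen after the data were seen; the others were planned. Receptor results kept their direction under both alternatives: as shares of V-segment UMIs, Trbv13-3 and the Trav14 family made up 14.1% and 23.3% at day 5, 5.77% and 24.3% late, 7.07% and 14.4% in the library labelled donor, and 89.0% and 86.03% in the library labelled endogenous. The Tcf7-gate difference was −14.2 (day comparison) and −3.35 points (recipients) without thinning, −3.12 at 3000 UMIs and −7.70 with a Slamf6 gate (both recipients); the Havcr2-gate difference was 1.19 and 5.94 without thinning and 11.6 and 3.42 at 3000 UMIs. A gate needs 1 UMI, so depth limits these shares, but these settings also change which cells are counted, and the cause of the changes was not tested.

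Of 312 list medians under alternatives, 296 stayed within their interval, 13 moved beyond it and 3 with an interval that left out 0 changed sign. A further 15 changed sign with an interval that held 0, the stem-like median late against day 5 among them (0.34, and −0.41 among cells without a cell-cycle UMI). Among cells without a cell-cycle UMI, late against day 5, the interferon-stimulated median was −0.0547 (reversed), cell cycle −1.24, glycolysis −0.30, oxidative phosphorylation −0.32, immediate early genes 0.57, mitochondrially encoded genes −0.49 and MHC class I 0.54; between the recipients' libraries, cell cycle was 0.11 and oxidative phosphorylation −0.0152 (reversed). With the mean of cell CPM, mitochondrially encoded genes were −0.64 (day) and 0.17 (recipients), oxidative phosphorylation −0.0200 (recipients, reversed) and MHC class I 0.0652. The B-cell median was −1.09 (day) and 0.83 (recipients) without the filter on other cell types, by that filter's own construction, and −0.41 (recipients) with stricter filters. Of 336 log2 folds of named genes, 263 stayed within their interval, 73 moved and none changed sign. Apart from the B-cell list, the cause was not tested.

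In the gate contrast, counts stayed within 1.5 times the reported ones with DESeq2, size factors, no gene filter, thinned gates, the Slamf6 gate, doublets kept and no filter on other cell types, but were 171 and 89 without the library block. Leaving out each library gave 527 to 2684 genes up and 575 to 2752 down, the lowest without the library labelled donor (527 and 575), then labelled endogenous (601 and 648) and late (1124 and 1183). No list kept its call with an estimated correlation: adjusted p was 0.0738 for stem-like genes, 0.454 for inhibitory receptors, 0.433 for exhaustion factors, 0.313 for cytotoxic genes, 0.367 for homing, 0.419 for cell cycle, 0.313 for interferon-stimulated genes, 0.375 for glycolysis, 0.432 for mitochondrially encoded genes, 0.375 for the B-cell list and 0.367 for the NK list. Without the block, adjusted p was 0.0953 for glycolysis and 0.0998 for the B-cell list; without the filter on other cell types it was 0.0911 for the B-cell list and 0.0274 for chemokines. Leaving out each library gave adjusted p of 0.00191 to 0.0662 for exhaustion factors (lost without late, 0.0534, or labelled endogenous, 0.0662), 0.0438 to 0.711 for circulating effectors (gained without day 5), 2.43e-05 to 0.833 for chemokines (gained without labelled donor, 0.00248, or labelled endogenous, 2.43e-05), 0.0295 to 0.0709 for glycolysis (lost without day 5, 0.0709, or labelled donor, 0.0563), 0.0130 to 0.261 for oxidative phosphorylation (gained without day 5), 0.00532 to 0.0828 for the B-cell list (lost without late) and 3.96e-04 to 0.159 for the NK list (lost without day 5). Of 288 values for named gate genes, 266 kept their call and 22 lost it, none with a change of sign: 14 genes, Gzma, Gzmb, Ccl3 and Ccl4 among them, without the block, and Xcl1, Ms4a4c and Gpr183 without the gene filter or without a recipients' library. The cause was not tested.

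Between the recipients' libraries, the difference in stem-like clusters was −8.91 points at a resolution of 1.2, −11.95, −13.0 and −12.0 over the 3 other random starts, −11.99 without the cell-cycle list and −7.17 with doublets kept. Terminally differentiated-like clusters had −3.94 at 1.2, −1.08 at the third start and −0.638 with doublets kept, and effector-like clusters 8.46 at 1.2, 8.49 at the second start and 8.41 with doublets kept. Cycling clusters had 6.35 at 0.5, 4.94 at 1.2, and 4.98 and 4.92 at the second and the third start. Interferon-responding clusters had −7.09 at 1.2, −2.05, −0.0853 and −4.65 over the starts, −4.72 without the cell-cycle list and −6.15 with doublets kept. Unnamed clusters had 6.43 at 1.2 and 3.33 at the third start, and changed sign at the first start (−0.706) and with doublets kept (−1.89). All differences in stem-like, terminally differentiated-like, effector-like, cycling and interferon-responding clusters kept their sign under these alternatives, but the interval included 0 for terminally differentiated-like clusters at the third start (−2.25 to 0.0880) and with doublets kept (−1.76 to 0.485), and for interferon-responding clusters at the second start (−0.854 to 0.674). The naive-like class was not found at 0.5. The cause was not tested.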

Other observations

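All tests of explanations in this part were chosen after the results were seen. The share of cells with a transcript at equal depth separated the recipients' libraries in circulating-effector genes. A Cx3cr1 UMI was seen in 12.1% of cells of the library labelled donor and 5.41% of the library labelled endogenous, a Klrg1 UMI in 4.68% and 0.744%, and a Gzma UMI in 38.8% and 19.5%. Il7r, which keeps memory cells alive, was seen in 10.8% and 15.1%, and Id3 in 17.1% and 22.8%. At day 5, Mki67 was seen in 51.8% of cells, against 5.18% late, and Cd101, a marker of terminal exhaustion, in 0.729% against 10.7%. Across genes, the late library correlated with the recipients' libraries at 0.929 and 0.938, and the day 5 library at 0.795 and 0.736.

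The receptor of the recipients' libraries went against their labels. A single wrong label would leave both libraries mostly Trbv13-3, but the library labelled donor had 11.1%, which argues against it. Free receptor RNA would leave Trbv13-3 a minority of a cell's beta UMIs, but it took 100% in the median cell of the library labelled endogenous, which argues against it too. Exchanged labels require both libraries to be out of place, and with 94.8% Trbv13-3 in the library labelled endogenous both were. An exchange of labels may therefore lie behind the pattern. The names of the deposited files for these libraries, which do not come from the counts, go against the labels too. An exchange was not tested further, and no biological explanation was tested.

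Effector-like cells made up 9.24% of the library labelled donor and 0.0327% of the library labelled endogenous. Natural killer cells would lack receptor transcripts, but 97.7% of the cluster's cells in the library labelled donor held a beta V UMI. Cd8b1 stood at 1826 CPM there and the NK receptor Ncr1 at 0.182 CPM. These values argue against natural killer cells as most of the cluster. Other genes of the NK list were higher in it than in the library's other cells, Klrb1c at 180 against 2.06 CPM among them. Fcer1g stood at 30.9 against 1.87 CPM and Tyrobp at 10.4 against 2.01 CPM. The receptor's V segments alone are argued against as well, since 12.8% of cells in the library labelled donor with the P14 segments were effector-like (48 of 376, 9.56 to 16.6), against 1 of 7535 in the library labelled endogenous, and so are the doublet calls, since the library labelled endogenous had 0.0480% with doublets kept. Under exchanged labels this may be a difference between host cells and P14 cells that began in acute infection. However, cell origin, the paired receptor, the sort of the donor cells before transfer and the transfer itself stay open and untested. Among the 11 most frequent beta segments of the library labelled donor the share ran from 1.94% of cells with Trbv1 to 25.7% of cells with Trbv16.

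Outside the receptor loci, 7 of 5367 genes at 20 CPM in both gates were lower in the library labelled donor by at least 0.9 on the log2 scale in each gate: Wdfy1, Vax2, Pianp, Podnl1, Gm47015, Tmem181a and Dynlt1b, chosen after their values were seen. By the same rule 7 were higher (Zeb2, Car2, Mki67, Hist1h1b, Hist1h2ae, Hist1h2ab and Gzma). Pianp had −2.54 in the Tcf7 gate and −2.45 in the Havcr2 gate, and Wdfy1 −1.50 and −1.57. Over all kept cells, each of the 7 lower genes was highest in the library labelled endogenous. In the order day 5, late, labelled donor and labelled endogenous, Pianp stood at 0, 0.531, 0.715 and 26.6 CPM, and Wdfy1 at 6.65, 11.2, 8.69 and 33.9. Podnl1 was also high in the late library, at 54.0 CPM against 58.1 in the library labelled endogenous. A different mix of cell states was tested within clusters among the 5802 and 4549 cells outside both gates, which had no part in the choice of the genes. It is argued against for the 7 lower genes, since the log2 ratio closest to 0 was −1.18 (Vax2, −1.36 to −1.01). For the higher genes it stays open in part: the ratio fell from 1.09 to 0.11 for Mki67 and from 1.11 to 0.05 for Hist1h1b, but was 1.39 for Car2, 1.14 for Zeb2 and 0.99 for Gzma. No other explanation was tested for them. For Dynlt1b, a shift of counted reads from one copy to another is argued against, since the summed Dynlt1 family had −0.88. Reads that could not be given to a single copy may be missing from that sum, so a difference in mapping stays open. A single linked region is argued against, since the 7 lower genes lie on 5 chromosomes, although Tmem181a and Dynlt1b lie within 1 Mb of each other on chromosome 17 (3.99% of random sets held as many neighbours). A strain difference spread over the genome between host and donor may contribute; it stays open and was not tested.

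Lists of other cell types served as checks on contamination. B-cell genes had a median log2 fold of 0.74 late against day 5 (4 measured, with Ighm at 44.0 and 82.1 CPM) and −0.40 between the recipients' libraries, and between gates 2 of 4 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0299, adjusted p = 0.375 with an estimated correlation; 0.0828 without the late library). Myeloid genes had −0.16 and 0.02, and 2 of 7 fell between gates, with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.533). The NK list, which shares Gzma and Eomes with T-cell lists, had 2.16 and 1.37, and 2 of 4 fell between gates, the same adjusted over the list alone (camera adjusted p = 0.0307, adjusted p = 0.367 with an estimated correlation; 0.159 without the day 5 library). CD4 T-cell genes, which include Ctla4 and Il2ra, had 0.14 late against day 5 with a mean below 0, too few measured members in the recipients, and 2 of 3 up between gates, the same adjusted over the list alone (camera adjusted p = 0.0983). No erythroid gene reached the minimum, and sex-linked genes had 2 measured members, too few for a median; every library held Xist.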
